A study of Sus scrofa with 10 samples.

How the data were processed

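Gene expression was measured in 10 RNA samples from sorted porcine fetal fibroblasts, 5 SSEA-1 positive and 5 SSEA-1 negative fractions, on Affymetrix porcine arrays with biotin-labelled cRNA. Per the labels' protocols, the fibroblasts came from day 24 embryos of Danish Landrace/Yorkshire x Duroc crosses, were sorted by magnetic beads, and total RNA was extracted from each fraction. Per the series text, 5 biological replicates gave 5 positive and 5 negative fractions. Group and replicate number were taken from the sample titles, and every column of values was matched to a sample.

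The deposited values are log2 signals per probe set, made by the authors with RMA per the submitters' processing notes; the version and the background setting are not given in the sources used here. The log base was checked on the hybridisation controls, whose signal rose by between 0.942 and 1.05 per unit of log2 concentration across arrays, taking the supplier's concentrations as known. The lower end of the values lay near 0 with 4.55% to 8.16% of each array below 0, so a background was removed in a way that is not stated, and differences between dim probe sets are the least certain. Array medians ran from 1.15 to 1.19, and no further normalization was applied.

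Probe sets were named through the platform's annotation, updated by Entrez identifier against a RefSeq gene table of Sscrofa11.1 used for names only. Of 24123 probe sets, 10099 had 1 gene symbol, 198 had several and were not named, and the rest had none in that table; 9989 matched by identifier and no symbol was changed. They stood for 6765 genes, each represented by its probe set with the highest mean over all 10 arrays. For 5 genes, EPOR and RSAD2 of the lists among them, that was a control probe set for a pig gene, and none of the 5 passed in limma or had an unadjusted p under 0.05. Background was the 95th percentile of 23 control probe sets for sequences that should be missing.

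Fractions were compared in limma 3.58.1 under R 4.3.3 with lmFit and eBayes on all probe sets, the 188 controls included, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A second count required at least a 1.5-fold difference. Gene lists, 34 with 1091 distinct genes of which 583 were measured, 8 through a synonym, were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. List means and control levels were compared by exact two-sided permutation tests over the 252 assignments of 5 against 5 arrays, whose smallest p is 0.00794. These tests do not use the replicate numbers. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined; the exceptions are stated where they are used.

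Named genes were the 12 largest rises and 12 largest falls among representative probe sets with 1 symbol, past the threshold and with non-overlapping fractions, placeholder symbols left out, and up to 4 members of each list with the smallest p. FUT4 and FUT9 were also to be named. Genes named outside this rule are said to have been chosen after their values were seen.

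The replicate numbers were treated as pairs. The series text reads as each replicate giving both fractions, and the deviations of same-numbered arrays from their fraction means correlated at 0.214, 0.580, 0.356, 0.119 and 0.247 for replicates 1 to 5, each over 0.1. For replicate 4 the pairing is the least certain, since both of its arrays correlated better with an array of another number, as did the negative array of replicate 5, at up to 0.314. The block was an alternative and not part of the test above.

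The alternatives were the replicate block as a fixed or random effect, eBayes with trend and robust settings, array weights, median centring, repeated quantile normalization, cyclic loess, filters on level and on interquartile range, an exact rank-sum test, thresholds of 0.01 and 0.1, the mean over a gene's probe sets, and leaving out each array or each pair. Fits without controls and with the poly-A level as covariate, alone and with the replicate block, were added after the data were seen. No positive array had a level as low as any negative one, so differences with this covariate are extrapolated by the model. List means were also compared with that covariate, by permuting the residuals of a fit on the level alone 100000 times. The procedure was tested on simulated data with the real means and spread of the 24123 probe sets, 200 of them changed and the measured G2/M genes lowered 1.5-fold besides. Of the 200, 88.0% of those changed 1.5-fold and 98.0% of those changed 2-fold were recovered, and 16 unchanged probe sets, 7.66% of the calls, were called. The recovery rates cover the 200 alone and cannot be taken for the lowered G2/M genes, whose calls were not counted apart. The simulated noise was independent between genes and held no replicate effect, unlike the real arrays, so these rates need not hold for them.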

Results

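Porcine fetal fibroblasts, cultured from fetal tissue without the head at day 24, were divided by magnetic sorting with an antibody against SSEA-1, the Lewis X carbohydrate that marks several embryonic and stem cell types on the cell surface. RNA from 5 SSEA-1 positive and 5 SSEA-1 negative fractions was measured on Affymetrix porcine arrays, 1 array per fraction, and both fractions carried replicate numbers 1 to 5. Each array gave log2 signals for 24123 probe sets, of which between 69.3% and 72.5% lay above the background level of 0.352 set by control probe sets for sequences that should be missing from the sample. The arrays resembled each other closely, with correlations across probe sets of 0.991 to 0.996 within a fraction and 0.987 to 0.995 between fractions. The number of arrays limits the precision of every value below.

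The comparison asked how gene expression differed between the SSEA-1 positive and negative fractions. BASP1, a membrane-associated growth cone protein, rose 3.04-fold in the positive fraction, from a mean log2 signal of 2.56 ± 0.48 to 4.17 ± 0.12 (SD, n = 5 each). NUDT4, a diphosphoinositol polyphosphate phosphatase, rose 2.38-fold and the pro-apoptotic gene BAX rose 2.08-fold. CTR9, a subunit of the PAF1 transcription elongation complex, fell by 0.98 on the log2 scale, and the splicing factor SRSF3 fell by 0.84. In all, 1495 probe sets changed at an adjusted p under 0.05 in limma, 656 higher and 839 lower in the positive fraction, and with the replicate number as a block the count was 2832, with 1246 higher and 1586 lower. Of the 1495 probe sets, 58 were array controls, all of them higher, which left 598 higher and 839 lower probe sets that are not controls.

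Most differences were small. The median size among the 1437 changed probe sets that were not controls was 0.44 on the log2 scale, or 1.36-fold, and 42 of them reached 2-fold, 28 higher and 14 lower. At least 1.5-fold was reached by 316 of them, 144 higher and 172 lower, or by 355 probe sets when the controls are counted. Over all 23935 probe sets that are not controls, changed or not, the 5 values of a fraction lay wholly above or below those of the other for 1507, or 6.30%, where chance alone gives 0.794%. At the level of genes, each read from its brightest probe set, 217 rose and 283 fell among 6765, 500 in all. The replicate block gave 382 higher and 583 lower genes, 965 in all. Repeating quantile normalization turned the balance, with 273 higher and 219 lower genes, and cyclic loess gave 273 higher and 224 lower, so the larger number of falls depended on the scaling. Among probe sets that are not controls these scalings gave 725 higher and 688 lower and 732 higher and 709 lower, and at 1.5-fold or more 161 against 136 and 158 against 150. The 1.5-fold balance also turned without positive replicate 1, without negative replicate 1, 3 or 5, and without both arrays of replicate 1, 3 or 5, with 122 higher and 87 lower without replicate 1. In other settings it leaned further to falls, with 153 higher and 267 lower with the replicate block. Without negative replicate 2 there were 196 and 317, and without both arrays of replicate 4 147 and 250. The balance of genes turned without negative replicate 1, at 174 higher and 159 lower, and without both arrays of replicate 1, at 80 and 67. The probe set count was 850 without SSEA-1 positive replicate 1, 853 without positive replicate 5, and 836 both without negative replicate 3 and without negative replicate 5.

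The other 9 of the 12 largest rises among genes whose fractions did not overlap were mixed in kind. COL1A2, a chain of type I collagen, rose by a log2 difference of 1.19 ± 0.13 (SE, adjusted p = 0.000434), and its other probe set, too near background to show a change, read 0.54 against 0.46. GATA6, a transcription factor of endoderm and mesoderm, rose by 0.86 ± 0.12 (SE, adjusted p = 0.00141), and TIMP3, an inhibitor of matrix metalloproteases, rose by 0.84 ± 0.12 (SE, adjusted p = 0.00207), with 0.73 on a second probe set that also passed. FBXO32, a muscle-enriched ubiquitin ligase component, rose by 0.91 with 0.92 on its other probe set. DDB1, a DNA damage-binding protein, POLR1E, a subunit of RNA polymerase I, and ERGIC1, a protein of the ER-Golgi intermediate compartment, rose by 0.86, 0.92 and 0.83, and the other ERGIC1 probe sets rose by 0.40 and 0.65. SRRM2, a splicing-associated protein, rose by 1.06, whereas its second brightest probe set differed by 0.18 at an adjusted p of 0.181 and the remaining 3 were dim. EP400, a chromatin remodeller, rose by 0.82, and its other probe set was near background at 0.54 against 0.51. The call of each of the 12 held without any single array or pair. With the level of the poly-A spike-in controls on each array as a covariate, a fit chosen after the data were seen, the calls of BAX, DDB1 and AAED1 held and those of the other 46 of the 49 named genes with a call ended. With the replicate block beside the covariate none of the 49 passed in limma and 27 had an unadjusted p under 0.05. Among the 12 rises TIMP3 read 0.51 ± 0.21 with the covariate and 0.355 ± 0.25 with both, and with both BASP1 read 2.46 ± 0.40 and BAX 1.64 ± 0.30 (SE).

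**Figure D1:**
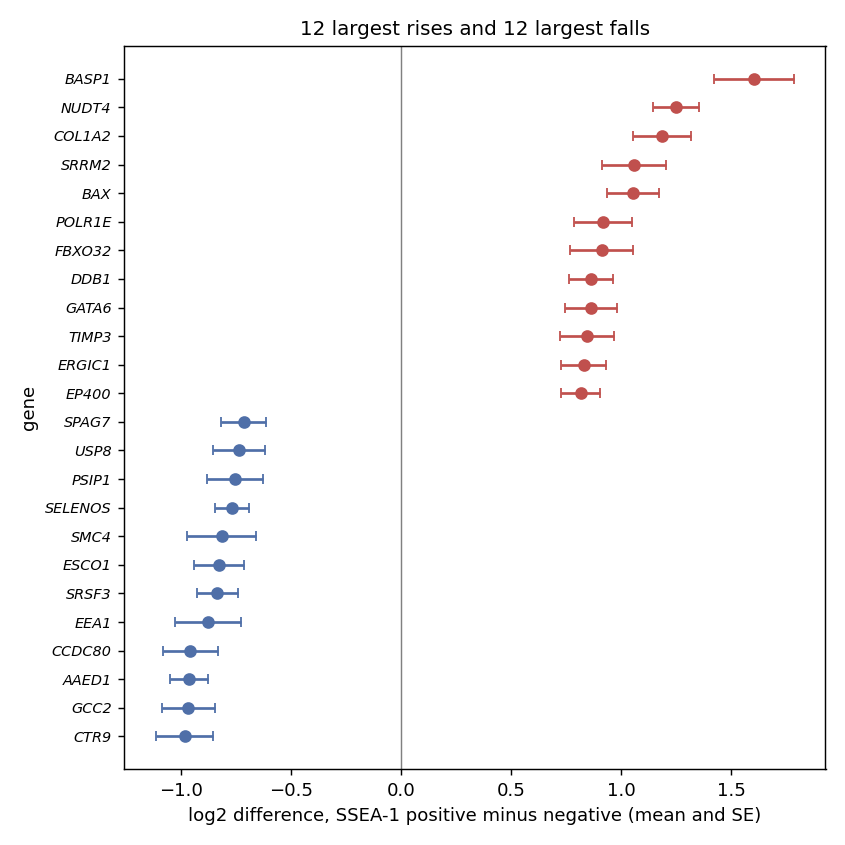
Log2 difference (SSEA-1 positive minus negative, with its standard error from limma, n = 5 arrays per fraction) on the horizontal axis for 24 genes, named on the vertical axis. They are the 12 with the largest rise and the 12 with the largest fall among named genes past the threshold whose fractions do not overlap. Rises run from 0.82 for EP400 to 1.60 for BASP1, and falls from -0.72 for SPAG7 to -0.98 for CTR9.

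The 12 largest falls among genes whose fractions did not overlap were likewise mixed in kind. The cell cycle genes CENPF and CDC45, given below, passed and fell further, by 1.44 and 1.10, but their fractions overlapped. GCC2, a golgin of the trans-Golgi network, fell by 0.97 and EEA1, an early endosome tethering protein, fell by 0.88, with -0.74 on the second EEA1 probe set. USP8, a deubiquitinase that acts at endosomes, fell by 0.74. ESCO1, an acetyltransferase of cohesin, fell by 0.83 and the condensin subunit SMC4 fell by 0.82 ± 0.16 (SE, adjusted p = 0.0103), with -0.52 on its second probe set, which also passed. PSIP1, a chromatin-bound coactivator, fell by 0.76 with -0.39 on its other probe set, which did not pass, SELENOS, a selenoprotein of the ER membrane, fell by 0.77, SPAG7 fell by 0.72 with -0.73 on its other probe set, and AAED1 fell by 0.97. CCDC80, a secreted matrix protein, fell by 0.96 on its brightest probe set, and its other probe set gave -0.12. The second CTR9 probe set, near background, gave -0.17. SMC4 was the only one of the 12 whose call was lost in leave-outs, namely without replicate 1 and without replicate 5 of both fractions. With the poly-A covariate 5 of the 12 were smaller by over 1.5 times: ESCO1 at -0.43 ± 0.18, USP8 at -0.39 ± 0.20, EEA1 at -0.53 ± 0.26, GCC2 at -0.62 ± 0.205 and CCDC80 at -0.63 ± 0.215 (SE). With the block beside it they read -0.13, -0.20, -0.35, -0.29 and -0.45, and PSIP1 read -0.18 ± 0.235 and SPAG7 -0.45 ± 0.23 (SE).

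Genes of the G2 and M phases read lower in the positive fraction, with 25 of 26 measured members lower and a median log2 difference of -0.60. CENPF, a kinetochore protein, fell by 1.44 ± 0.28 (SE, adjusted p = 0.0105), and SMC4 and the spindle checkpoint gene BUB3, which fell by 0.40, also passed. The other 23 did not pass, among them HMMR at -1.29 with an adjusted p of 0.0591 (0.000895 with the replicate block). Adjusted over the list alone, 5 members fell. With the replicate block, 20 of the 26 fell. The list passed camera at an adjusted p = 3.57e-05 with the preset correlation, but the adjusted p = 0.853 with an estimated correlation, and fry gave 0.361 (0.0116 with the block). The list mean was lower in 5 of 5 pairs, with pair differences of -0.378 to -0.812, and read 4.09 ± 0.42 against 4.69 ± 0.56 (SD, n = 5 each). An exact two-sided permutation test, which ignores the pairs, gave p = 0.0952, or 0.405 adjusted over the 34 lists. The median was -0.40 without SSEA-1 positive replicate 2, and 13 members fell without negative replicate 2; the call of BUB3 ended in 6 of 10 single-array leave-outs, positive replicate 5 among them, and that of CENPF without both arrays of replicate 1, 3 or 5. With the poly-A covariate the median was -1.46 and camera gave an adjusted p = 6.67e-12 (0.394 with an estimated correlation), while none of the 26 passed in limma and 20 had an unadjusted p under 0.05. With the replicate block beside that covariate the median was -0.98 and camera gave 3.17e-09 (adjusted p = 0.705 with an estimated correlation), but CENPF read -0.42 ± 0.32 (SE). BUB3 read -0.69 ± 0.17 (SE) with the covariate alone.

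Genes of G1/S and DNA replication followed with a median of -0.25, and 18 of 19 measured members were lower. CDC45, part of the replicative helicase, was the single member that fell, by 1.10 ± 0.29 (SE, adjusted p = 0.0421), and it lost that call in 8 of 10 single-array leave-outs, all but those of positive replicate 3 and negative replicate 2; its second probe set read -0.46 without passing. CDC45 read -2.14 ± 0.44 with the poly-A covariate and with the block beside it -1.91 ± 0.37 (SE). Adjusted over the list alone 3 members fell, and with the replicate block 7 fell, including RRM1 and FEN1. Camera gave an adjusted p = 0.0165, and the adjusted p = 0.853 with an estimated correlation, while fry gave 0.419 (0.0288 with the block). The list mean was lower in 5 of 5 pairs, with pair differences of -0.168 to -0.494. An exact two-sided permutation test, which ignores the pairs, gave p = 0.159, or 0.405 adjusted over the lists. Camera's call ended without positive replicate 2, at 0.129, without negative replicate 3, at 0.0813, and without negative replicate 4, at 0.107, in a leave-out range of 4.2e-05 to 0.129, and the median was -0.13 without positive replicate 2 and -0.42 without negative replicate 2. It also ended with the filter on level, at 0.0686, and with that on interquartile range, at 0.114, whereas the poly-A covariate gave a median of -0.93 and 9.8e-07 (0.419 with an estimated correlation), with none of the 19 past limma's threshold and 11 at an unadjusted p under 0.05, and with the block beside it a median of -0.45 and 0.00293 (0.705 with an estimated correlation). The same arrays differed in their poly-A spike-in controls, whose level relative to the hybridisation controls was 0.82 higher on the log2 scale in the positive fraction.

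The amino acid and ER stress list was also lower, with 18 of 22 measured members down and a median of -0.14. XBP1, a transcription factor of the unfolded protein response, fell by 0.45 ± 0.06 (SE, adjusted p = 0.00200), CRELD2, a secreted ER stress-inducible protein, fell by 0.33, and ATF4, the transcription factor of the integrated stress response, fell by 0.31 while its dim second probe set read 0.05. The remaining 19 did not pass, and adjusted over the list alone 6 fell. Camera gave an adjusted p = 0.0213, and the adjusted p = 0.853 with an estimated correlation, whereas fry gave 0.0228. The list mean was lower in 5 of 5 pairs with an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 arrays can give, or 0.135 adjusted over the 34 lists. Camera's call ended without positive replicate 1, at 0.0811, without both arrays of replicate 1, at 0.0576, and without both of replicate 2, at 0.0542, in a leave-out range of 0.00608 to 0.0811. It ended too with the mean of all probe sets of a gene, at 0.0766, with the filter on level, at 0.081, with that on interquartile range, at 0.545 with a median of -0.20 over 13 members, and with the poly-A covariate, at 0.263, or 0.573 with the block beside it. The median was -0.125 with the covariate and -0.09 with both, and the difference of the list mean was -0.08 ± 0.05 with the covariate (SE; permutation p = 0.185) against -0.13 ± 0.03. ATF4 read -0.13 ± 0.15 with the covariate and -0.04 ± 0.21 with both (SE), and the call of CRELD2 ended without both arrays of replicate 1, 3 or 5. These 3 lists were all that passed camera among 34, and 65 of 100 splits of the 10 arrays gave as many lists, among them 4 of the 12 other splits that part all 5 pairs.

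Among CDK inhibitors, p53 targets and senescence genes, 5 of 20 measured members rose and none fell. BAX rose by 1.05, ZMAT3, a p53-induced RNA-binding protein, by 0.71, the cell cycle inhibitor CDKN1A by 0.68 and IGFBP5, an insulin-like growth factor binding protein, by 0.67. The remaining one, PHLDA3, a p53-induced inhibitor of AKT, rose by 0.43 and was named after its value was seen. The same 5 passed when adjusted over the list alone, while CDKN1B at -0.30 and GADD45B at -0.40, also named after their values were seen, did not pass. The list as a whole did not pass camera (adjusted p = 0.101) or fry (0.0744, or 0.0403 with the replicate block), and 9 of the 20 members read lower. The list mean was higher in 5 of 5 pairs, at 4.56 ± 0.05 against 4.41 ± 0.07 (SD, n = 5 each), with an exact two-sided permutation p of 0.0238, or 0.202 adjusted over the 34 lists. Its difference was 0.23 ± 0.07 (SE; permutation p = 0.0214) with the poly-A covariate against 0.15 ± 0.04. Camera passed it without negative replicate 2, at 0.0395, in a leave-out range of 0.0395 to 0.25, and with the poly-A covariate, at 0.0265 (0.394 with an estimated correlation), where the median was 0.19 against 0.06 but 1 member passed against 5 and IGFBP5 read 0.21 ± 0.22 (SE); with the block beside the covariate the adjusted p was 0.304. Without both arrays of replicate 1 or of replicate 5, 3 members rose, and IGFBP5 did not pass.

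**Figure D2:**
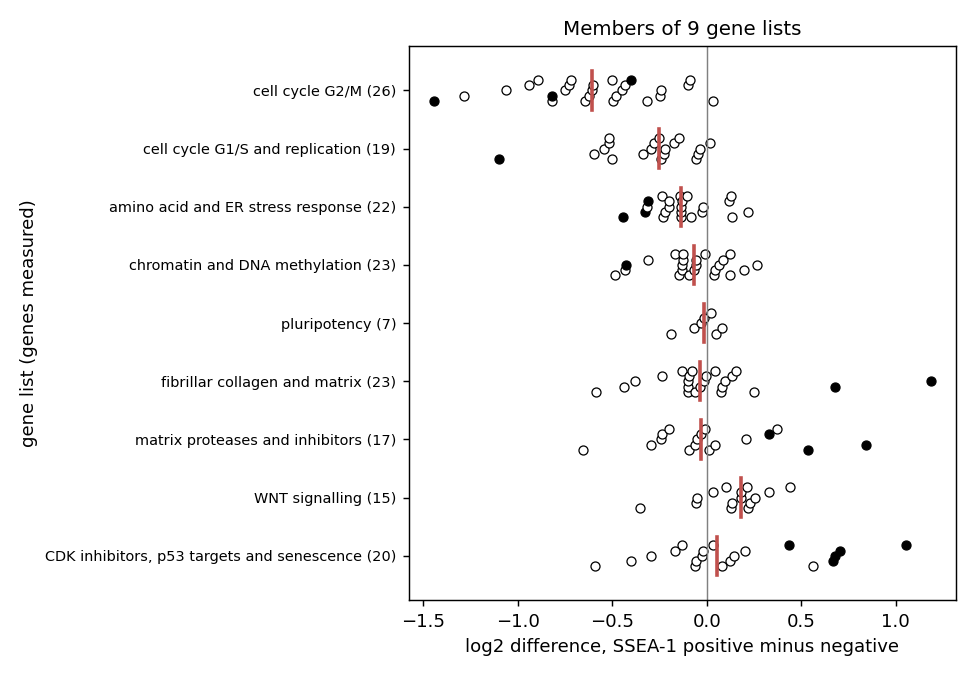
Log2 difference (SSEA-1 positive minus negative) of each measured member of 9 gene lists, 1 point per gene, with the number of genes measured in parentheses. Filled points passed an adjusted p under 0.05 in limma, open points did not, vertical bars mark list medians, and the G2/M list lies farthest to the left with a median of -0.60.

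In the matrix lists a few members passed, and no list as a whole passed camera. Of 17 proteases and inhibitors, 3 rose, all of them metalloprotease inhibitors: TIMP3, TIMP2 by 0.54 (0.35 on its other probe set) and TIMP1 by 0.33, while MMP13, below the background level on all 10 arrays, differed by 0.21 at an adjusted p of 0.0627. Adjusted over the list alone 4 rose, and with the replicate block 4 rose and 1 fell. Of 23 fibrillar collagen and matrix genes, COL1A2 and COL5A2 rose, COL5A2 by 0.68 with -0.04 on its dim other probe set, and the median of the list was -0.04. The same count rose when adjusted over the list alone, and 3 rose and 2 fell with the block. The call of TIMP1 ended without both arrays of replicate 1, 3 or 5, and that of COL5A2 without both of replicate 5. With the poly-A covariate the 3 inhibitors were all smaller by over 1.5 times, TIMP3 at 0.51 ± 0.21, TIMP2 at 0.33 ± 0.17 and TIMP1 at 0.165 ± 0.13, whereas COL5A2 read 1.03 ± 0.245 and, with the block beside it, 1.48 ± 0.25 (SE). POSTN, a matricellular protein, read -0.59 at an adjusted p of 0.0948 (0.000737 with the block). None of the 11 EMT regulators passed in limma, with or without the block, and 1 lay at an unadjusted p under 0.05. Camera adjusted p-values were 0.569, 0.818 and 0.588 for these lists in the order given.

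Genes of pluripotency and of the SSEA-1 glycan gave no call over all probe sets. None of 7 measured pluripotency genes passed in limma or had an unadjusted p under 0.05, which does not show that they were equal, and POU5F1 read 0.52 ± 0.14 against 0.44 ± 0.17 (SD, n = 5 each), near the background level. MYC read 6.01 ± 0.27 against 5.96 ± 0.28 (SD, n = 5 each). Of the 10 measured glycan genes none passed over all probe sets, 2 lay at an unadjusted p under 0.05, and adjusted over the list alone B4GALT1, a galactosyltransferase, was higher by 0.30 and GMDS, an enzyme of GDP-fucose synthesis, was lower with -0.24. With the replicate block both passed over all probe sets, at adjusted p-values of 0.0263 and 0.0450. No probe set carried the symbol FUT4 or FUT9, the fucosyltransferases that complete the Lewis X structure, so neither was analysed here. None of 5 primordial germ cell genes passed in limma or at an unadjusted p under 0.05, and 3 of them lay below the background level on all arrays of at least 1 fraction.

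Markers of other cell types gave few calls. Among 15 mesenchymal stem cell genes NR2F1, a nuclear receptor, rose by 0.36, and THY1, a surface glycoprotein, differed by 0.34 at an adjusted p of 0.0564 on its brightest probe set (0.0146 with the replicate block), by 0.89 at 0.000329 on another and by -0.00485 on the last. MYL9, a myosin light chain, was the only 1 of 19 smooth muscle and myofibroblast genes to rise, by 0.52, and ERG, an endothelial transcription factor, was the only 1 of 16 endothelial genes to fall, by 0.42. Second probe sets fell in limma for TPM1 of the smooth muscle list (-0.35, adjusted p = 0.0155) and ALCAM of the mesenchymal list (-0.30, adjusted p = 0.0472). The brightest probe sets of these genes did not pass. With the poly-A covariate MYL9 read 0.20 ± 0.23 and ERG -0.09 ± 0.18, and with the block beside it MYL9 read 0.24 ± 0.31 and ERG turned to 0.106 ± 0.255 (SE). Of 20 adipogenic genes, CEBPD and PNPLA2 rose by 0.35 and 0.40, and ADIPOR2 and PLIN2 fell by 0.35 and 0.56, while the second brightest probe sets of CEBPD and ADIPOR2 each read 0.01. GATA6 was the only call among 23 hepatic and visceral endoderm genes, WWP2, which fell by 0.56, among 10 chondrogenic genes, and ATF4 among 12 osteogenic genes. No member passed in limma among 18 epithelial, 7 mesothelial and urogenital, 23 haematopoietic, 21 skeletal myogenic and 15 neural and neural crest genes, of which 4, 0, 1, 3 and 2 lay at an unadjusted p under 0.05. With the block 1 epithelial and 1 skeletal myogenic gene rose, and 2 mesenchymal stem cell and 2 smooth muscle genes rose. Adjusted over the list alone, 2 mesenchymal stem cell genes rose, 3 adipogenic genes rose and 2 fell, and the other cell type lists kept the counts given. EPCAM read 0.44 ± 0.09 against 0.20 ± 0.15 (SD, n = 5 each), near the background level, at an adjusted p of 0.105. Low signal limits several of these lists. At least 1 array of each fraction lay above background for 9 of 23 haematopoietic, 10 of 23 hepatic, 10 of 16 endothelial and 4 of 7 mesothelial genes. The same held for 18 of 18 epithelial genes, though EPCAM and CDH1 averaged below the background level in the negative fraction. Camera passed none of these cell type lists. The calls of ERG, MYL9, WWP2, ATF4, ADIPOR2, PNPLA2 and PLIN2 each ended in 4 or more of the 10 single-array leave-outs, positive replicate 5 among them, that of NR2F1 ended without both arrays of replicate 1, 2 or 5, and that of CEBPD without both of replicate 1, 3 or 5. CEBPD read 0.558 ± 0.125 and PLIN2 -0.914 ± 0.255 with the poly-A covariate, and with the block beside it NR2F1 read 0.58 ± 0.26 and PNPLA2 0.63 ± 0.23 (SE).

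Signalling, chromatin and immune lists held at most 2 calls each, and the metabolic lists below held none in limma. SMAD1, a BMP effector, was the only 1 of 22 TGF-beta and BMP genes to rise, by 0.29, and FGF2, a fibroblast growth factor, rose by 0.64 beside IGFBP5 among 19 FGF, IGF and hedgehog genes. HDAC1, a histone deacetylase, fell by 0.43 among 23 chromatin and DNA methylation genes, and DNMT1 read -0.43 at an adjusted p of 0.0624 on its brightest probe set (0.0149 with the replicate block), while a dimmer one passed with -0.57 at 0.0301. ASH2L also passed in limma on its dimmer probe set only, with -0.57 at an adjusted p of 0.0458. IL6 fell by 0.55 among 27 inflammatory cytokine genes, and IRF9, an interferon signalling factor, rose by 0.28 among 25 interferon response genes. None passed in limma among 15 WNT, 22 immediate early, 27 hypoxia and glycolysis, 16 cholesterol synthesis, 27 oxidative phosphorylation, 12 HOX and positional identity and 16 imprinted genes, of which 4, 2, 5, 1, 4, 1 and 2 lay at an unadjusted p under 0.05. With the replicate block 2 WNT, 2 hypoxia and glycolysis, 1 immediate early and 1 cholesterol synthesis genes rose, and 1 oxidative phosphorylation gene fell. The block also gave 3 falls among chromatin genes, 2 rises and 1 fall among cytokine genes, and 1 rise and 1 fall among TGF-beta and BMP genes, the same as this last list gave when adjusted alone; adjusted over the list alone the other signalling and metabolic lists kept the counts given. The calls of SMAD1, FGF2 and IRF9 ended in 8, 7 and 7 of the 10 single-array leave-outs, positive replicate 5 among them, and that of IL6 without both arrays of replicate 1 or 5. IL6 read -0.98 ± 0.16 with the poly-A covariate, and with the block beside it -0.96 ± 0.28, where HDAC1 read -0.22 ± 0.23, IRF9 0.06 ± 0.23 and SMAD1 0.46 ± 0.24 (SE). WNT genes had a median of 0.18 and a camera adjusted p of 0.0968, in a leave-out range of 0.0395 to 0.257, and passed without positive replicate 4, at 0.0477, without negative replicate 2, at 0.0395, and without both arrays of replicate 5, at 0.0457. With an estimated correlation the adjusted p = 0.853 for WNT genes, or 0.546 with the block. Fry gave 0.0744 for WNT and 0.0738 for FGF, IGF and hedgehog genes, and 0.0288 for both with the block. Their list means were higher in 5 of 5 pairs, with exact two-sided permutation p-values of 0.0159 for WNT and 0.00794 for FGF, IGF and hedgehog genes, or 0.180 and 0.135 adjusted over the 34 lists.

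The control probe sets differed between the fractions as well. Poly-A spike-ins, bacterial transcripts added to the RNA before labelling, read 3.70 ± 0.48 in the positive and 2.46 ± 0.40 in the negative fraction (SD, n = 5 each), with an exact two-sided permutation p of 0.00794. Hybridisation controls, added after labelling, read 6.90 ± 0.16 and 6.48 ± 0.16 (SD, n = 5 each) with the same exact p. Probe sets for 28S ribosomal RNA read 9.13 ± 0.44 and 7.51 ± 0.33, and those for 18S read 6.06 ± 0.18 and 5.54 ± 0.24 (SD, n = 5 each), again with an exact p of 0.00794 and higher in 5 of 5 pairs. The poly-A level relative to the hybridisation controls ran from -3.452 to -2.658 on positive arrays and from -4.323 to -3.805 on negative ones. These ranges do not overlap, so values with this level as a covariate, here and above, are extrapolated. With it 12 probe sets passed in limma and 2930 had an unadjusted p under 0.05. Of the 1437 changed probe sets that are not controls 1416 had the same sign in that fit, with a median size of 0.405 against 0.439 and a median standard error of 0.173 against 0.0942. Single genes moved both ways: of the 49 named genes with a call, 12 were smaller by over 1.5 times and 6 were larger, and with the block beside it 15 were smaller and 8 larger. With the replicate block beside the covariate 4 probe sets passed and 2706 had an unadjusted p under 0.05, and 1281 of the 1437 had the same sign, with a median size of 0.379 and a median standard error of 0.243. With the covariate alone camera passed 8 lists, G2/M and G1/S lower and, higher, the p53 list, immediate early (median 0.66, adjusted p = 9.8e-07), epithelial (0.01), cholesterol synthesis (0.0131), HOX (0.0266) and cytokine genes (0.0350), but none with an estimated correlation or with fry.

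**Figure D3:**
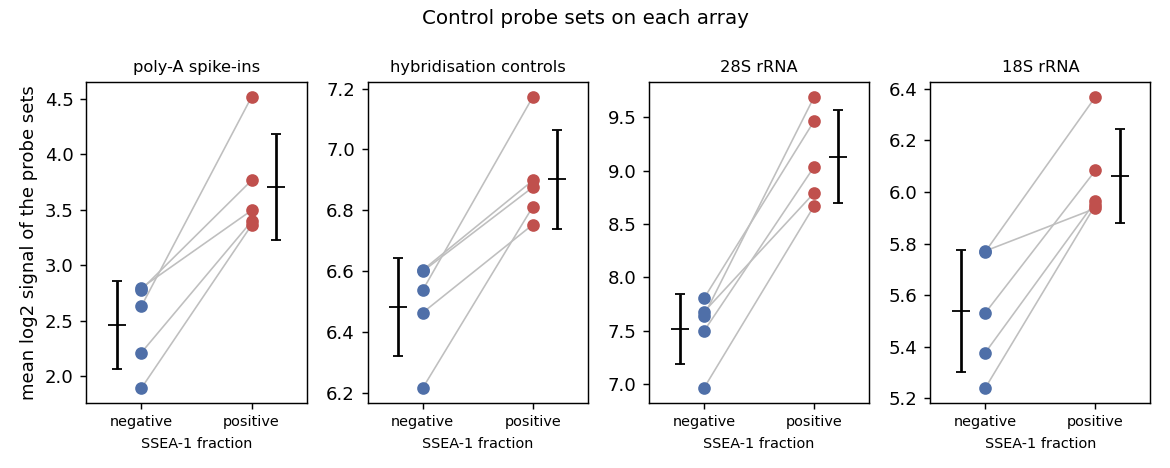
Mean log2 signal of 4 kinds of control probe set (vertical axes, each with its own range) on each array, by SSEA-1 fraction, with grey lines joining arrays of the same replicate number and black marks giving mean and SD (n = 5). Each kind was higher on the positive array in 5 of 5 pairs.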

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

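The tests of the poly-A controls below were chosen only after the difference was seen. A gap of an array to the rest of its fraction was tested for 368 groups of 5 log2 signals, of genes chosen by the fixed rule and of list means, and 19 stood out where chance gives about 18.4.

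In the SSEA-1 positive fraction, signals above the other arrays were those of replicate 1 for AAED1 (2.50), replicate 2 for B4GALT1 (5.02) and replicate 3 for LHX1 (0.391), and the imprinted list mean of replicate 4 (3.58). Signals below the others were those of replicate 1 for CDH11 (8.50), replicate 3 for USP8 (3.09), replicate 4 for TCF7L2 (0.534) and replicate 5 for ASH2L (2.01), with the list means of primordial germ cell genes in replicate 3 (0.430) and adipogenic genes in replicate 4 (2.55). In the negative fraction, replicate 4 lay above the others for EP400 (1.41), NR5A1 (1.12) and IGF2R (0.849), and below them for ADIPOR2 (2.93), SMAD4 (6.30) and TCF7L1 (3.89). Replicate 2 lay above for CNN2 (5.08), replicate 3 for NR2F1 (2.05) and replicate 5 for FGF7 (2.11).

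Spike-in and ribosomal RNA controls, which measure no messenger RNA of the pig, differed between the fractions: the 28S ribosomal RNA signal was 1.62 higher on the positive arrays, and the poly-A spike-ins exceeded the hybridisation controls by 0.825 more there, both on the log2 scale. Array-wide brightness or scaling that moves all signals alike would have left that 0.825 near 0, which the exact two-sided permutation p of 0.00794 argues against. The hybridisation controls did not move alike, differing by 0.549 for bioB, the dimmest, and 0.214 for cre, the brightest. Each poly-A control differed by more, from 0.93 for lys to 1.38 for dap, which was about as bright as bioC at 0.454. Whether a shift that depends on signal accounts for a part was not tested. Less sample poly-A RNA relative to the spike-in may account for the 0.825, since it needs a difference of this sign, but the value was known before the test. A larger amount of spike-in added to the positive samples would give the same poly-A reading. That alone would not raise the ribosomal RNA signal, which was higher in 5 of 5 pairs, by 1.62 for 28S and 0.52 for 18S. Whether the ribosomal signal had a separate cause was not tested. More degraded RNA would raise the 3′ minus 5′ signal of actin, GAPDH and EF1A in the positive fraction, and no such rise was seen. That signal read 0.79 ± 0.03 against 0.80 ± 0.05 (SD, n = 5 each), a difference of -0.0121 with an exact permutation p of 0.627. This does not show that it was equal, so a small difference in degradation stays open. The sort itself, as a biological difference in RNA content per cell, was not tested.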

How the results depend on the processing

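The fits without controls and with the poly-A level, alone or with the block, were chosen after the data were seen. The replicate block gave 2832 changed probe sets and 965 genes as a fixed effect, and 2561 and 895 as a random effect; 1486 of the 1495 probe sets passed in both the unblocked and the fixed-effect fit with the same sign, no list gained or lost its camera call, and no named gene lost its call; calls gained stand beside their results. Stricter and looser thresholds of 0.01 and 0.1 gave 400 and 2430 probe sets. An exact rank-sum test gave 0, with 3560 probe sets at an unadjusted p under 0.05, because its smallest p of 0.00794 is too coarse to survive adjustment over all probe sets. With the poly-A level as covariate 12 probe sets, 12 at 1.5-fold or more, 6 genes and 8 lists passed, and 9 of the 12 probe sets were among the 1495. The median difference of the 1495 was 0.445 without and 0.394 with the covariate, and 1452 kept their sign; calls ended mainly because the standard error grew, by a median of 1.89 times, since the level correlates at 0.848 with the fraction and 7 residual degrees of freedom are left in place of 8. With that covariate, an estimated correlation gave 0 lists and fry gave 0. With the covariate and the replicate block together there were 4 probe sets, 4 at 1.5-fold or more, 1 gene and 5 lists, or 0 lists with an estimated correlation and 0 with fry, and ERG turned to 0.106, for which the cause was not tested. Of the 2832 probe sets of the block alone 2468 kept their sign in that fit, with a median size of 0.343 against 0.389 and a median standard error of 0.243 against 0.0795. For lists, an estimated correlation gave 0 (3 with the preset one), and 0 with the block as well. Fry gave 1, or 6 with the block. The filter on level gave 1 and the filter on interquartile range gave 1, with fewer genes tested in the filtered fits. Leaving out arrays or pairs gave 384 to 1834 probe sets, 219 to 551 at 1.5-fold or more, 115 to 663 genes and 2 to 5 lists. Leaving out SSEA-1 positive replicates 1 and 5 singly gave 280 and 268 genes, and negative replicates 1, 3 and 5 singly gave 333, 268 and 273; without negative replicate 2 there were 551 probe sets at 1.5-fold or more and 5 lists. Without both arrays of replicates 1, 3 and 5 the probe sets numbered 481, 461 and 384 and the genes 147, 142 and 115, and without replicates 3 and 5 those at 1.5-fold or more numbered 223 and 219. Why single arrays moved the counts was not tested. All other alternatives lay within 1.5 times, with 1398 probe sets when controls were left out. The 49 named genes with a call kept their side of the threshold in 1120 of 1421 comparisons with an alternative and lost it in 300, and the remaining 1 was the change of sign of ERG. Of the 300 losses, 49 came from the exact rank-sum test, which no probe set could pass. The poly-A covariate gave 46 more alone and 48 with the block, so the pooled count is not a measure of how stable the calls were. G2/M genes passed the list test in 28 of 34 alternatives, all 15 leave-outs included, with adjusted p-values of 1.31e-14 to 0.853. No value could be given for FUT4 and FUT9. Signal over background limits the dimmest genes: near the level of 0.352 a difference is the least certain.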

Other observations

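The search over gene-symbol families, the comparison of probe sets of the same gene and the tests of G2/M genes with the poly-A level as covariate and on pair differences were chosen after results were seen, and the genes in the next paragraph were named after their values were seen.

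Several symbol families of splicing factors, none of them a list fixed before the data were examined, held mostly lower members in the SSEA-1 positive fraction, each with an adjusted p = 0.940 in camera with an estimated correlation. All 9 measured PRPF genes, parts of the spliceosome, were lower, and 5 of them fell: PRPF39 by 0.81, PRPF4B by 0.45, PRPF38B by 0.41, PRPF4 by 0.37 and PRPF38A by 0.35. Of 11 SRSF splicing factors 8 were lower, and SRSF3 and SRSF4 fell by 0.84 and 0.40. Of 17 HNRNP genes 15 were lower, and HNRNPDL, HNRNPR and HNRNPF fell by 0.67, 0.42 and 0.24, whereas HNRNPL read 0.36 at an adjusted p of 0.0663 (0.0125 with the replicate block, where 7 SRSF and 5 HNRNP genes fell). All 9 nucleoporin genes sharing the NUP symbol were lower and none passed in limma, with 5 falling in the replicate block. The SF family, also of splicing factors, went the other way in its median of 0.07, with 3 of 8 genes lower, all 3 of which fell, and SRRM2 rose. The directions of the PRPF, SRSF, HNRNP and NUP families held under median centring, repeated quantile normalization and cyclic loess.

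Camera over 84 symbol families of 8 or more genes passed 4, all of them lower: PRPF at an adjusted p of 0.00134, and HNRNP, SRSF and the nucleoporins at 0.0197 each. All 4 were lost with an estimated correlation, and the SF family gave 0.896. Exact two-sided permutation tests of the family means gave 0.0635 for HNRNP, lower in 4 of 5 pairs, and 0.0238 for SRSF, 0.00794 for PRPF and 0.0317 for the nucleoporins, each lower in 5 of 5. The splicing-factor families were picked because they read lower, so these values do not test whether they do. Chance division of the arrays cannot be excluded for the search: 40 of 100 splits, the real one included, gave 4 or more families, and up to 12, as did 4 of the 12 other splits that part all 5 pairs, and HNRNP, SRSF and PRPF passed together in 1 direction in 12 of the 99 other splits.

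The probe set and gene counts were higher for the real division of the arrays than for any other split drawn. The real division was the only 1 of 100 splits with as many changed probe sets, 1495 against at most 14 in the others. The same held for 1.5-fold changes, with 1 of 100 splits and 355 against 11, and for genes, with 1 of 100 splits and 500 against 8. Chance division of the arrays cannot be excluded for the number of lists past camera: 65 of 100 splits gave 3 or more, and up to 10. Among the 12 other drawn splits that also part all 5 pairs, the highest counts were 0 probe sets and 5 lists, and 4 gave 3 or more lists. With the replicate numbers taken as pairs only such splits are a fair comparison, 16 in all with the real one. They are too few to exclude chance division for the probe set and gene counts as well.

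The lower G2/M signal did not rest on a single sort replicate, since the list mean difference of -0.60 ran from -0.55 to -0.66 when each pair was left out. Whether the amount of sample RNA drove it stays open: within the fractions the list mean and the poly-A level had r = 0.489 over 10 arrays (permutation p = 0.171; Spearman's rho 0.430, permutation p = 0.260), and r = 0.236 without the 2 arrays farthest from the median. The sign of the within-fraction slope goes against it without excluding it, predicting a difference of 0.70. With the poly-A level as covariate the list mean difference was -1.30 ± 0.55 (SE, permutation p = 0.0562) against -0.60 ± 0.31. Camera's adjusted p of 6.67e-12 held at the preset correlation only (0.394 with an estimated one). Within pairs the difference was -0.60 ± 0.07 (SE, n = 5 pairs), with an exact sign-flip permutation p of 0.0625, the smallest that 5 pairs allow. Extrapolated to an equal poly-A level it was -0.78 ± 0.24 over all pairs, but -0.39 ± 0.33 (SE) without replicate 4, whose pairing is the least certain. The slope within pairs was 0.21 ± 0.27, where -0.73 would account for the whole difference. No pair had an equal level, the differences in it running from 0.422 to 1.25, and the fractions did not overlap in it. The values with the covariate or at an equal level therefore cannot decide the question. A lower share of dividing cells may be an explanation the sort provides, and it was not tested.

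Signal specific to a probe set would leave a gene's brightest other probe set no more likely to share the direction than by chance. For higher calls 77.4% of 146 genes shared it, and for lower calls 84.8% of 191 did (one-sided exact binomial p = 9.51e-12 and 6.58e-24). These shares argue against signal specific to a probe set as the whole account. The test counts genes as independent, but all were read on the same arrays, so its p-values may be too small. That the brightest other probe set stood for the gene was settled when the test was run. The other probe set itself passed in limma in the same direction for 18 of the 146 genes and 41 of the 191, and in the opposite one for 2 and 1. The median difference of the other probe set was 0.11 against 0.46 for higher calls and -0.19 against -0.43 for lower ones. The called probe set was the passing one with the smallest p, so selection alone favours a larger difference on its side. The gap therefore does not measure disagreement between probe sets. Single genes such as SRRM2, whose second probe set was well above background and did not pass in limma, stay uncertain. For COL1A2 and EP400 the other probe set was too dim to tell.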
